A study of Mus musculus with 18 samples.

How the data were processed

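Gene counts were taken from the 1 deposited table, which holds 54352 gene symbols in 18 libraries of mouse pro-B cells. The cells were sorted on surface markers that include CD19 and high CD43 and exclude CD2 and surface immunoglobulin. RNA-seq was made from total RNA of WT (n = 3) and Mettl14 KO (n = 2) cells at 0 h and after 6 h with IL-7, with the same numbers at each time. m6A-seq (input n = 2, IP n = 2) was made from fragmented poly(A) RNA and YTHDF2 RIP-seq (input n = 2, RIP n = 2) from RNA bound to YTHDF2, both from WT cells. Per the submitters' processing notes, base calls were made with CASAVA, reads were trimmed with Trim Galore and aligned with HISAT2 2.1.0 to mm10, and reads per gene were counted with featureCounts, with settings not given in the sources used here. The deposited values, read counts per gene made by the authors, were treated as estimated counts, because 50 symbols hold values that are not whole (226 cells). The step that made these is not described, and they were rounded. All columns were matched to a sample. Of the symbols 53749 (98.9%) were found in the gene name table, and 26 symbols that look like dates were kept as they stand. Gene positions, where given, are those of GRCm38.p6.

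Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries scaled with TMM factors, and quasi-likelihood fits with 1 mean per group were made apart for RNA-seq (16033 genes, 10 libraries), m6A-seq (14309 genes, 4 libraries) and RIP-seq (11892 genes, 4 libraries). The common biological coefficient of variation was 0.593, 0.194 and 0.373. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Contrasts were KO against WT at each time, 6 h against 0 h in each genotype, the difference of these responses, IP against input and RIP against input. Levels in the text use the same scaling, except those of pseudogenes, and of Mettl14 beside them, under Other observations, which are counts over the library total without TMM factors. Libraries with 3 counts or fewer over a group are given as counting ratios with 95% intervals, and groups at 0 counts as bounds with a floor of 3 counts over the group. Prior counts of 2 were used for log levels. A level of 1 CPM stands for 15.6 to 24.2 counts in an RNA-seq library, 13.6 to 16.4 in an m6A-seq library and 6.18 to 9.50 in a RIP-seq library. Replicates differed by more than counting error in every group (8.64 to 167 times the counting variance), so no library was a copy of another.

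Gene lists were tested with camera (limma 3.58.1) at a fixed inter-gene correlation of 0.01, with p adjusted over the lists of a kind that held at least 5 measured genes. There were 23 fixed lists of gene groups and 12 of cell-type markers, written from general knowledge before the data were examined. Further genes of a list are counted at an adjusted p under 0.05 over the list alone. Each call is also given with the correlation estimated from the data. Values with fry test the list against no change and not against the other genes, as camera does. Sets of m6A-enriched and YTHDF2-bound genes (adjusted p under 0.05, higher than input) were tested in the KO contrasts with camera over 4 tests, and genes induced or repressed in the mean IL-7 response in the difference of responses. Overlaps are set against the number expected by chance from the list sizes.

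The genes named in the text follow a rule fixed at the same stage. It takes Mettl14, Mettl3, Wtap, Ythdf2, Il7r, Myc, Cish, Mki67 and Rag1 throughout, and per contrast the 6 largest rises and falls among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between groups. Predicted genes, clone names, pseudogenes of ribosomal proteins, immunoglobulin and T cell receptor segments and snoRNA, snRNA and microRNA names were left out of that part. It adds up to 4 genes of smallest p from each list with a call or with at least 3 members past the threshold, the 5 genes of smallest p in both the m6A and the YTHDF2 set, and the 10 of smallest p for the difference of responses. Genes outside it are said to have been picked later.

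Replicate numbers were checked for pairing by the correlation of deviations from group means. WT libraries at 0 h and 6 h with the same number gave 0.34, 0.23 and 0.14. Those with other numbers gave -0.32 to 0.20, and 2 of them (2 and 3 crossed, 0.205 and 0.197) lay above the third pair. All same-number pairs were over the limit of 0.1 used here and were taken as pairs in WT, which the values and labels leave open. Of the m6A-seq libraries, the input and IP of replicate 1 hold Y-linked transcripts and those of replicate 2 Xist, so the number also marks the sex of the mice there. Fits with the number as a block are given where they change a call of a list or of a gene in the text.

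The steps were tested on simulated counts drawn from real means with known changes in up to 200 genes. Of genes changed 4-fold 70% were recovered for KO against WT at 0 h and 73.3% at 6 h. For IL-7 it was 55% in WT and 63.3% in KO, for the difference 46.7%, for m6A 81.7% and YTHDF2 50%. In the same order, 2-fold changes gave 27%, 29%, 29%, 14%, 4%, 44% and 24.0%. False calls were 5.50, 1.01, 9.71, 2.30, 6.45, 11.9 and 14.1% of calls in turn. Far more genes were called for m6A and YTHDF2, whose rates may differ.

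Alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 2 libraries, an absolute log2 fold change above 1, and library sizes without mitochondrial, ribosomal, small RNA and immunoglobulin genes. Further ones were fits of only the groups compared, 1 model for the 8 m6A-seq and RIP-seq libraries, replicate blocks, each library left out in turn, estimated inter-gene correlations, fry, other list sizes, 10000 random lists matched on expression and the partial correlation given input levels. Where leaving out 1 library left a group with 1, that library is assumed to vary as the others do. No absolute amount of RNA was measured, so all changes are relative to the other genes of a library.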

Results

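RNA abundance was measured in 18 libraries of mouse pro-B cells, the B-cell precursors that rearrange the immunoglobulin heavy chain locus. The RNA-seq part held 10 libraries, described as made from total RNA. These were wild-type (WT) cells at 0 h (n = 3), Mettl14 knockout (KO) cells at 0 h (n = 2), WT cells after 6 h of culture with IL-7 at 15 ng/mL (n = 3) and KO cells after the same culture (n = 2). METTL14 is a subunit of the enzyme that writes N6-methyladenosine (m6A) on mRNA, and IL-7 is the cytokine that drives pro-B cell growth. The m6A-seq part held m6A immunoprecipitates (IP, n = 2) and their inputs (n = 2) from WT cells. The YTHDF2 RIP-seq part held RNA bound to the m6A reader YTHDF2 (n = 2) and its inputs (n = 2), also from WT cells. Total counts per library were 15.6 to 24.2 M in RNA-seq, 13.6 to 16.4 M in m6A-seq and 6.18 to 9.50 M in RIP-seq. Levels are CPM (counts scaled to a library of 1 M), given as mean ± SD over the libraries of a group, and log2 fold changes are given ± SE with the adjusted p of the edgeR fit. Intervals and floors cover counting error only. The labels do not say whether replicates were separate animals or cultures, so the p-values measure the spread between these samples. Coordinates are those of GRCm38.p6, the assembly also called mm10.

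Mettl14 (chromosome 3, 123368295 to 123385990) was lower in each of the 4 KO libraries than in each of the 6 WT RNA-seq libraries. At 0 h it stood at 10.5 and 18.1 CPM in KO and at 61.9, 56.6 and 45.7 CPM in WT. After 6 h of IL-7 it stood at 13.6 and 19.2 CPM in KO and at 53.4, 59.4 and 58.3 CPM in WT. The log2 fold change of KO against WT was -1.93 ± 0.29 at 0 h (adjusted p = 0.00538) and -1.79 ± 0.29 at 6 h (adjusted p = 0.00390). Without KO 0 h replicate 1 the value at 0 h was -1.60 and no longer passed the threshold. IL-7 left Mettl14 at a log2 fold change of 0.06 ± 0.24 in WT (adjusted p = 0.941). Its partner Mettl3 gave -0.58 ± 0.24 in KO against WT at 0 h (adjusted p = 0.473) and -0.47 ± 0.24 at 6 h (adjusted p = 0.349).

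**Figure D1:**
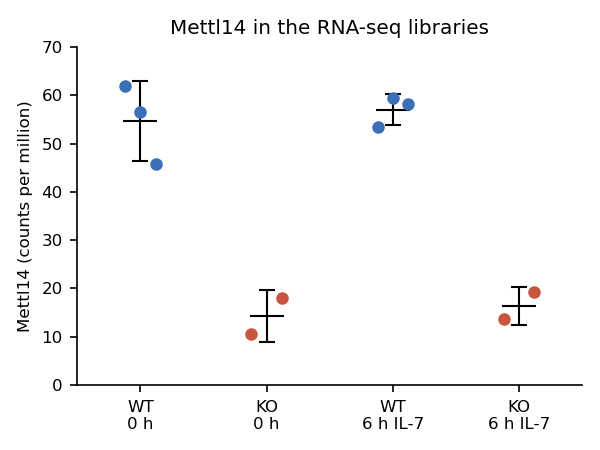
Normalised Mettl14 level in CPM in each RNA-seq library (points), with the mean and SD of each group (bars; WT n = 3, KO n = 2 at each time). The 4 KO libraries lie between 10.5 and 19.2 and the 6 WT libraries between 45.7 and 61.9.

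KO and WT cells at 0 h were compared to ask which transcripts differ without METTL14 before IL-7 is added. KO cells held more of the growth regulator Myc (135 ± 2.63 against 58.0 ± 10.2 CPM, log2 fold change 1.22 ± 0.19, adjusted p = 0.00700, chromosome 15, 61985341 to 61990361). Its relative Bmyc rose too (2.12 ± 0.40, adjusted p = 0.0258), as did the cell-cycle gene Ccnd2 (0.96 ± 0.18, adjusted p = 0.0271). The lymphotoxin gene Ltb rose from 30.5 ± 9.24 CPM in WT to 133 ± 21.0 CPM in KO (log2 fold change 2.12 ± 0.26, adjusted p = 9.93e-04, chromosome 17, 35194507 to 35196305). The NF-kB genes Birc3 (0.91 ± 0.17, adjusted p = 0.0311) and Nfkb2 (0.88 ± 0.18, adjusted p = 0.0430) also rose. Rasgrp1, which couples antigen receptors to Ras, was nearly absent from KO libraries. It had 1 count in KO and 649 in WT, a ratio of 425 (95% counting interval 76.0 to 16815, chromosome 2, 117279983 to 117342877, adjusted p = 9.93e-04).

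Across all 16033 genes tested at 0 h, 37 rose and 21 fell in KO. Other large rises were in the potassium channel gene Kcng1 (1.85 ± 0.28), the chemokine receptor gene Cxcr5 (1.83 ± 0.30), the protease inhibitor gene Serpinb1a (1.64 ± 0.22) and Lrp4 (1.62 ± 0.27). The transcription factor genes Hivep3 (1.27 ± 0.19) and Pou2f2 (1.23 ± 0.19) rose as well, and so did Ccnl2 (0.87 ± 0.16). Transcripts of these genes were enriched over input in the m6A IP and the YTHDF2 RIP of WT cells. Falls were found in the collagen gene Col5a3 (-4.11 ± 0.61), BE692007 (-3.74 ± 0.45), the actin nucleator gene Fmn2 (-3.36 ± 0.67), Zfp827 (-2.76 ± 0.48), the long non-coding RNA Mirt1 (-1.01 ± 0.18) and Ciita (-2.69 ± 0.53), which drives MHC class II genes. Il7r stood at 306 ± 24.9 against 282 ± 24.7 CPM (adjusted p = 0.915) and Mki67 at 2349 ± 857 against 2141 ± 176 CPM (adjusted p = 0.918).

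Of the fixed gene lists, the ATF4 and integrated stress response list was higher in KO at 0 h. None of its 31 measured members passed over all genes, 4 rose and 0 fell adjusted over the list alone, and the median log2 fold change was 0.36 (adjusted p = 8.57e-06, and 0.0332 with an estimated correlation). Slc7a5 (0.90), Shmt2 (0.71) and Trib3 (1.35) are examples. NF-kB targets were higher, with 2 of 20 members up, 4 adjusted over the list alone and a median of 0.49 (adjusted p = 6.13e-05, and 0.161 with an estimated correlation). IL-7 and STAT5 targets were higher, with 2 of 22 up, 3 adjusted over the list alone and a median of 0.12 (adjusted p = 0.0257, 0.313 with an estimated correlation, and 0.0615 with the replicate number as a block). That call was lost without WT 0 h replicate 2 (0.181), KO 0 h replicate 1 (0.275) or KO 6 h replicate 1 (0.0576), and 0.258 without the libraries rich in Gm42418. MYC and ribosome biogenesis genes were higher with a median of 0.27 over 40 members and no single call (adjusted p = 1.69e-04, 0.555 with an estimated correlation, and 0.201 without KO 0 h replicate 2).

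Pre-B differentiation genes were lower in KO at 0 h. Of 30 members 0 rose and 1 fell, 1 and 3 adjusted over the list alone, with a median of -0.28 (adjusted p = 1.69e-04, 0.313 with an estimated correlation, and 0.0676 without KO 0 h replicate 2). Cd2, a surface antigen of pre-B cells that the sort selected against, fell by 2.67 on the log2 scale (0.940 ± 0.415 against 6.01 ± 1.79 CPM, adjusted p = 0.0471), and Ikzf3 stood at -1.05 ± 0.22 (adjusted p = 0.0501). Genes of G1/S and DNA replication were lower with a median of -0.38 over 38 members (adjusted p = 4.07e-06, 0.555 with an estimated correlation, 0.0564 without WT 0 h replicate 1, and 0.0615 without the sparsest libraries). G2/M and mitosis genes were lower with a median of -0.26 and 6 of 36 down adjusted over the list alone (adjusted p = 4.81e-06, and 0.623 with an estimated correlation). Interferon-stimulated genes were lower with a median of -0.47 and 4 of 38 down adjusted over the list alone (adjusted p = 9.53e-05, and 0.672 with an estimated correlation), for example Mx2 (-2.17) and Ifit1 (-2.02). Per library the interferon list score in WT was -0.49 in replicate 1, below both KO libraries (-0.23 and -0.17), and 0.43 and 0.63 in the others. At 6 h the list stood at a median of 0.48 (adjusted p = 0.0507, 0.753 with an estimated correlation, and 0.0187 with the replicate block). It passed without WT 0 h replicate 1 (0.0180), KO 0 h replicate 1 (0.0445), WT 6 h replicate 2 (0.00199), KO 6 h replicate 1 (1.59e-04) or the libraries rich in Gm42418 (2.97e-04). The nuclear-encoded respiratory chain list was lower (-0.27 over 39 members, adjusted p = 0.00106, and 0.417 with an estimated correlation). Histone genes were called lower with a median of -1.12 over 29 members (adjusted p = 0.0337, 0.672 with an estimated correlation, and 0.0604 with the replicate block), with Hist1h2bh at 0 counts in KO and at least 12.4-fold lower (adjusted p = 0.569). That call was lost without WT 0 h replicate 2 (0.558) or 3 (0.0643) and without the libraries rich in Gm42418 (0.205). Genes of the mitochondrial genome were called higher with a median of 0.44 over 13 members (adjusted p = 0.0180, and 0.707 with an estimated correlation). This call was lost without WT 0 h replicate 2 (0.558) or 3 (0.131) or the libraries rich in Gm42418 (0.480), and had the other sign without KO 0 h replicate 1 (0.460).

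The count of 58 genes at 0 h was 257 with DESeq2, 307 with no filter on low counts, 32 with limma-voom and 6 in a fit of only the groups compared. It was 112 without the sparsest libraries and 23 without those rich in Gm42418. With single libraries left out it was 92 without WT 0 h replicate 1, 14 without replicate 2 and 36 without replicate 3, 15 without KO 0 h replicate 1, and 31 without WT 6 h replicate 2 or 3. Of the 22 genes past the threshold at 0 h that the naming rule picked, 5 passed whichever of the 10 libraries was left out: Ltb, Serpinb1a, Rasgrp1, Col5a3 and BE692007. With the replicate number as a block Bmyc (adjusted p = 0.0647), Cd2 (0.0712) and Nfkb2 (0.0544) did not pass at 0 h, and Ikzf3 did (0.0235).

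KO and WT cells after 6 h of IL-7 were compared to ask which transcripts differ while the cytokine acts. Transcripts of G2/M and mitosis were lower in KO. Of 36 measured members 24 fell and none rose, 35 fell adjusted over the list alone, and the median log2 fold change was -1.10 (adjusted p = 6.89e-40, and 0.110 with an estimated correlation). Top2a, which untangles DNA before division, stood at 666 ± 71.6 against 1518 ± 186 CPM (log2 fold change -1.19 ± 0.19, adjusted p = 0.00422, chromosome 11, 98992947 to 99024199). Ccnb2 (-1.92 ± 0.29, adjusted p = 0.00289), the spindle gene Nusap1 (-1.86 ± 0.30, adjusted p = 0.00588) and the cytokinesis gene Racgap1 (-1.42 ± 0.25, adjusted p = 0.00627) fell, and Mki67 stood at -0.74 ± 0.23 (adjusted p = 0.107). Per library, the median of the list on the log2 scale, centred on each gene's mean, was -0.34 and -0.60 in KO and 0.94, 0.35 and 0.69 in WT. In G1/S and DNA replication 3 of 38 members fell and none rose, 7 adjusted over the list alone, with a median of -0.34 (adjusted p = 1.67e-05, and 0.572 with an estimated correlation). Clspn (-1.34 ± 0.29), the histone mRNA binding protein gene Slbp (-0.83 ± 0.20) and Hells (-0.85 ± 0.22) were those 3.

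The ATF4 and integrated stress response list was higher in KO after 6 h. Of 31 members 4 rose and none fell, 8 rose adjusted over the list alone, and the median was 0.73 (adjusted p = 7.95e-11, and 0.00529 with an estimated correlation). The proline synthesis gene Aldh18a1 stood at 181 ± 12.1 against 77.5 ± 9.54 CPM (log2 fold change 1.23 ± 0.18, adjusted p = 0.00210, chromosome 19, 40550257 to 40588463). Atf5 (1.94 ± 0.36, adjusted p = 0.00929), the amino acid transporter gene Slc7a5 (1.14 ± 0.21, adjusted p = 0.00974) and Pck2 (1.12 ± 0.16, adjusted p = 0.00194) also rose. NF-kB targets were higher, with 3 of 20 members up, 6 adjusted over the list alone and a median of 0.52 (adjusted p = 4.29e-07, and 0.0736 with an estimated correlation). Nfkb2 (1.45 ± 0.18, 175 ± 25.4 against 64.0 ± 3.63 CPM), the apoptosis inhibitor gene Birc3 (1.32 ± 0.17, 222 ± 33.9 against 88.9 ± 6.88 CPM) and Cd40 (1.57 ± 0.38) were those 3. Ltb rose here too (2.19 ± 0.25, 290.1 ± 104 against 63.5 ± 9.62 CPM, adjusted p = 4.73e-04).

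Pre-B differentiation genes were lower in KO after 6 h. Of 30 members 1 rose and 4 fell, 3 and 6 adjusted over the list alone, with a median of -0.36 (adjusted p = 4.84e-04, 0.294 with an estimated correlation, and 0.0511 without the libraries rich in Gm42418). Rag1, the recombinase gene, stood at 375 ± 8.91 against 691 ± 77.9 CPM (log2 fold change -0.88 ± 0.19, adjusted p = 0.0229). Cd2 (-3.56 ± 0.57), Cd22 (-1.48 ± 0.28) and Ikzf3 (-0.94 ± 0.22) fell. The marker list of large cycling pre-B cells was lower (3 of 7 fell, 2 rose and 4 fell adjusted over the list alone, median -0.74, adjusted p = 0.00977, and 0.178 with an estimated correlation). It shares Top2a and Ccnb2 with the G2/M list. Its call was lost without KO 0 h replicate 2 (0.0686), KO 6 h replicate 1 (0.215) or the libraries rich in Gm42418 (0.287). In pro-B identity 2 of 28 members fell and none rose (median 0.01, adjusted p = 0.880).

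Among m6A writers, readers and erasers in KO after 6 h, Ythdf2 (233 ± 6.09 against 105 ± 10.1 CPM, log2 fold change 1.15 ± 0.19, adjusted p = 0.00541, chromosome 4, 132184916 to 132212256), Ythdf1 (1.07 ± 0.21) and Rbm15 (1.23 ± 0.24) rose and Mettl14 fell. The list as a whole had a median of 0.05 over 20 members (adjusted p = 0.308). IL-7 and STAT5 targets had 2 of 22 members up, 5 adjusted over the list alone (median -0.02, mean 0.06, test direction up, adjusted p = 0.162), and the STAT5 feedback gene Cish was one of them (0.93 ± 0.22, 231 ± 11.5 against 122 ± 12.3 CPM). MYC and ribosome biogenesis genes were higher (2 of 40 up, 3 adjusted over the list alone, median 0.25, adjusted p = 0.00504, 0.572 with an estimated correlation, and 0.304 without WT 6 h replicate 1), with Nop2 (0.89 ± 0.20) and Ppat (0.91 ± 0.20) past the threshold and Myc at 0.63 ± 0.19 (adjusted p = 0.0939). Cholesterol and lipid synthesis genes were lower (2 of 27 down, 1 up and 3 down adjusted over the list alone, median -0.33, adjusted p = 0.0106, 0.572 with an estimated correlation, 0.118 without KO 6 h replicate 1, and 0.116 without the libraries rich in Gm42418). The fatty acid elongase gene Elovl6 (-1.22 ± 0.19) and the desaturase gene Scd1 (-1.41 ± 0.35) were the pair that fell. The nuclear-encoded respiratory chain list was lower with no single call (median -0.24, adjusted p = 8.89e-04, and 0.393 with an estimated correlation). Of chromatin enzymes Tet3 (0.96 ± 0.19) and Setd1b (0.67 ± 0.17) rose and Ezh2 fell (-0.76 ± 0.19), with a list median of 0.07 (adjusted p = 0.880).

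Across all genes tested, 222 rose and 228 fell in KO after 6 h. Large rises outside the lists were in the collagen gene Col20a1 (4.32 ± 1.12), Dsel (2.30 ± 0.56), Sulf2 (2.29 ± 0.46), Tpst2 (2.23 ± 0.39) and the adaptor gene Lat (2.14 ± 0.26). Of genes enriched in both the m6A and the YTHDF2 libraries, Hivep3 (1356 ± 22.5 against 420.5 ± 6.51 CPM), the death ligand gene Tnfsf10 (1.54 ± 0.18), Pag1 (1.37 ± 0.18) and Sacs (1.15 ± 0.17) rose. Falls were in Col5a3, with 2 counts in KO and 664 in WT and a ratio of 192 (95% counting interval 52.8 to 1585), Rasgrp1 (-5.03 ± 0.69), the myosin light chain gene Myl4 (-3.65 ± 0.34), Lonrf3 (-3.19 ± 0.74) and the coagulation gene F5 (-3.06 ± 0.66). The count of 450 was 969 with DESeq2, 1025 with no filter, 965 in a fit of only the groups compared, 188 without the sparsest libraries and 180 without those rich in Gm42418. It was 895 without WT 0 h replicate 1, 178 without WT 6 h replicate 2, 89 without WT 6 h replicate 3, 190 without KO 6 h replicate 1 and 42 without KO 6 h replicate 2. Of the 47 genes past the threshold that the naming rule picked, 15 passed whichever of the 10 libraries was left out. With the replicate block Slbp (adjusted p = 0.0507), Hells (0.0696), Cd40 (0.0680), Scd1 (0.0964), Setd1b (0.0824) and Ezh2 (0.0669) did not pass at 6 h. Nor did Col20a1 (0.0804) and Dsel (0.0518).

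The differences between KO and WT overlapped between the times. These share no libraries, but WT libraries of the same number were correlated between the times. The numbers by chance assume independent contrasts, which these are not. Of the 37 genes that rose at 0 h, 27 also rose at 6 h, where 0.512 would be shared by chance, and of the 21 that fell 15 also fell (0.299 by chance). No gene rose at one time and fell at the other.

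**Figure D2:**
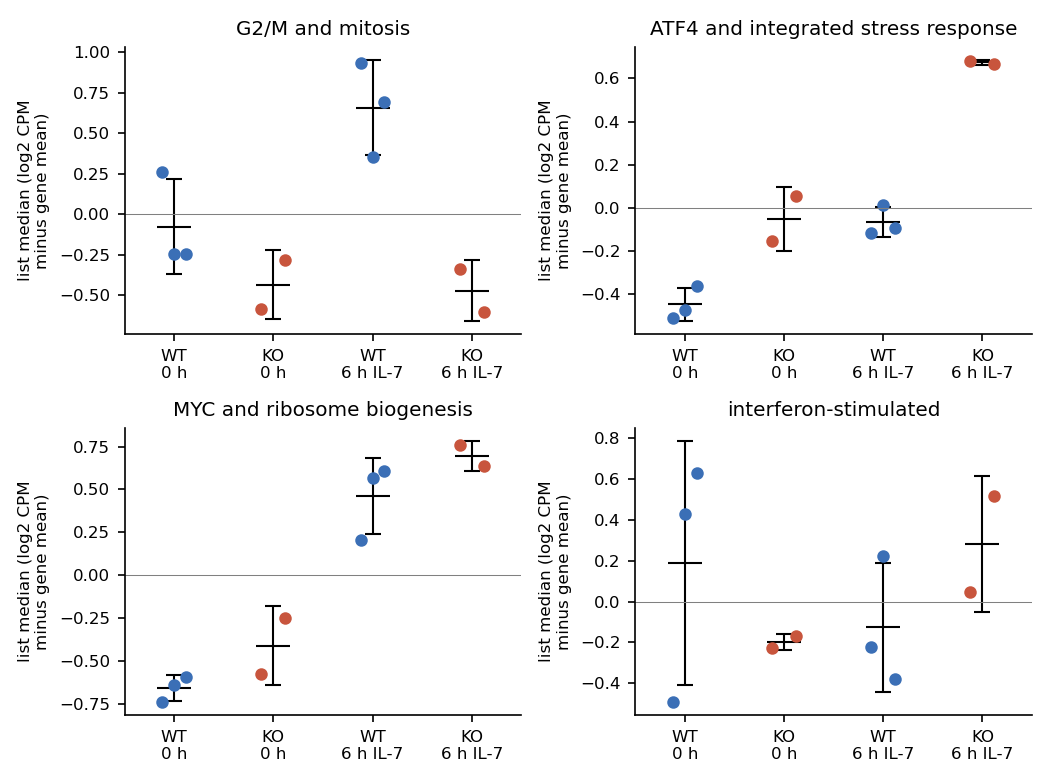
Median over the members of 4 fixed gene lists in each RNA-seq library (points; log2 CPM minus the mean of each gene over the 10 libraries), with the mean and SD of each group (bars; WT n = 3, KO n = 2 at each time). The G2/M values after 6 h are 0.35 to 0.94 in WT and -0.60 to -0.34 in KO, and the ATF4 values after 6 h are -0.12 to 0.01 in WT and 0.67 to 0.68 in KO.

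WT cells at 6 h and 0 h were compared to ask how pro-B cells respond to IL-7. The series holds no culture of 6 h without IL-7, so the response named here, in both genotypes, includes any effect of time in culture. Cholesterol and lipid synthesis genes rose. Of 27 members 19 rose and none fell, 22 rose adjusted over the list alone, with a median of 1.67 (adjusted p = 3.33e-54, and 0.00704 with an estimated correlation). The receptor gene Ldlr went from 17.4 ± 4.88 to 169 ± 21.0 CPM (log2 fold change 3.28 ± 0.22, adjusted p = 5.23e-07, chromosome 9, 21723576 to 21749919), and Hmgcs1 (2.33 ± 0.16), Fasn (1.89 ± 0.16) and Cyp51 (2.57 ± 0.22) rose with it. MYC and ribosome biogenesis genes rose, 30 of 40 over all genes and 39 adjusted over the list alone, with a median of 1.08 (adjusted p = 2.38e-45, and 0.0195 with an estimated correlation). Myc itself went from 58.0 ± 10.2 to 267 ± 39.1 CPM (2.20 ± 0.18, adjusted p = 3.19e-06), and Mybbp1a (1.59 ± 0.19), Rrp12 (1.62 ± 0.22) and Gnl3 (1.67 ± 0.24) are examples from the list.

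IL-7 and STAT5 targets were higher after IL-7 in WT. Of 22 members 8 rose and 2 fell, 9 and 3 adjusted over the list alone, with a median of 0.83 (adjusted p = 4.91e-10, and 0.00964 with an estimated correlation). Cish rose from 22.2 ± 4.31 to 122 ± 12.3 CPM (2.45 ± 0.21, adjusted p = 4.37e-06, chromosome 9, 107296659 to 107302784), and Socs2 (2.35 ± 0.23), Socs3 (3.92 ± 0.57) and the kinase gene Pim1 (1.83 ± 0.17) rose. Il7r itself fell from 282 ± 24.7 to 178 ± 40.6 CPM (-0.66 ± 0.17, adjusted p = 0.0286). Pro-B identity genes were lower, with 1 of 28 up and 12 down, 1 and 15 adjusted over the list alone, and a median of -0.56 (adjusted p = 4.14e-12, and 0.0208 with an estimated correlation). Rag1 fell from 2357 ± 504 to 691 ± 77.9 CPM (-1.77 ± 0.17, adjusted p = 1.15e-05, chromosome 2, 101638252 to 101649532), and Rag2 (-1.78 ± 0.20), Cd93 (-1.20 ± 0.17) and Blnk (-0.84 ± 0.15) fell. Pre-B differentiation genes were lower (1 of 30 up and 4 down, with the same counts adjusted over the list alone, median -0.26, adjusted p = 4.76e-04, and 0.179 with an estimated correlation), the homing receptor gene Sell falling (-1.51 ± 0.21) and Cd2 rising (1.86 ± 0.44).

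G2/M and mitosis genes were higher after IL-7 in WT. Of 36 members 15 rose and none fell, 27 rose adjusted over the list alone, with a median of 0.76 (adjusted p = 1.04e-16, and 0.213 with an estimated correlation). Top2a (1.14 ± 0.17), the kinesin gene Kif11 (1.10 ± 0.18) and Cdk1 (1.23 ± 0.23) rose. G1/S and DNA replication genes were lower, 7 of 38 falling and 13 adjusted over the list alone, with a median of -0.42 (adjusted p = 1.96e-06, and 0.440 with an estimated correlation), for example Gins2 (-1.10 ± 0.23) and Uhrf1 (-0.74 ± 0.17). The ATF4 list had 6 of 31 members up and 2 down, 11 and 2 adjusted over the list alone (median 0.40, adjusted p = 0.00351, and 0.0514 with an estimated correlation), Slc7a5 rising (1.48 ± 0.20) and Pck2 (-0.93 ± 0.15) and Ddit4 (-2.07 ± 0.36) falling. Heat shock and protein folding genes were higher (5 of 23 up and 1 down, 11 and 1 adjusted over the list alone, median 0.61, adjusted p = 7.32e-08, and 0.187 with an estimated correlation), with the unfolded protein response gene Xbp1 at 1.78 ± 0.17. Glycolysis and hypoxia genes were called higher with a median of 0.34 but a mean of -0.00 (6 of 26 up, 9 up and 1 down adjusted over the list alone, adjusted p = 0.00153, 0.242 with an estimated correlation, and 0.0713 without the libraries rich in Gm42418). Vegfa (2.28 ± 0.20) and hexokinase Hk2 (1.75 ± 0.31) rose.

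Histone genes were lower after IL-7 in WT with no single call (median -1.75, or -1.64 with genes at 0 counts set to their bound, adjusted p = 0.0114, 0.454 with an estimated correlation, 0.183 without WT 0 h replicate 2, and 0.0584 without the libraries rich in Gm42418). Hist1h2bg had 2 counts at 6 h and 174 at 0 h, a ratio of 88.4 (95% counting interval 24.1 to 736, adjusted p = 0.0602). Zinc finger and homeobox genes were lower (1 of 29 fell, 1 adjusted over the list alone, median -0.23, adjusted p = 0.0260, and 0.252 with an estimated correlation). That call was lost without WT 0 h replicate 1 (0.128), WT 6 h replicate 2 (0.114) or KO 6 h replicate 1 (0.0503), without the sparsest libraries (0.143) and without the libraries rich in Gm42418 (0.0650). The chromatin organiser gene Satb1 was the zinc finger and homeobox member that fell (-1.21 ± 0.16). Immediate early genes had a median of -0.24 (adjusted p = 0.0601). They passed with the replicate block (0.0238), without the libraries rich in Gm42418 (0.0129) or with WT 0 h replicate 2 (0.0102), KO 0 h replicate 1 (0.0361) or 2 (0.0365), WT 6 h replicate 1 (0.0218) or KO 6 h replicate 2 (0.0372) left out. Interferon-stimulated genes had a median of -0.44 (adjusted p = 0.0572). They passed without WT 0 h replicate 1 (2.77e-06), WT 6 h replicate 2 (0.00321), KO 6 h replicate 1 (0.0423) or 2 (0.0412), or the sparsest libraries (3.93e-07). Across all genes 466 rose and 474 fell. The largest rises included the orphan nuclear receptor gene Nr4a3 (24.6 ± 1.58 against 0.315 ± 0.183 CPM), Lta (14.8 ± 2.68 against 0.352 ± 0.225 CPM), Foxc1 (4.86 ± 0.78), Megf10 (4.74 ± 0.84) and Mpzl2 (4.65 ± 0.75, adjusted p = 0.0698 with the block within genotype). The largest falls included Fbp1 (-4.06 ± 0.94), Hmcn1 (-3.41 ± 0.67), Ccm2l (-2.83 ± 0.34) and Cass4 (-2.74 ± 0.48). The count of 940 was 1477 with DESeq2 and 1452 with no filter. It was 617 without WT 0 h replicate 3, 492 without WT 6 h replicate 2 and 425 without WT 6 h replicate 3, and 50 of 69 rule-picked genes past the threshold passed whichever library was left out. It was 497 with an absolute log2 fold change above 1 also asked for.

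KO cells at 6 h and 0 h were compared to ask how the response to IL-7 runs without METTL14. Cholesterol and lipid synthesis genes rose, 12 of 27 over all genes and 19 adjusted over the list alone, with a median of 1.03 (adjusted p = 6.72e-31, and 0.00914 with an estimated correlation). Ldlr went from 13.5 ± 2.42 to 160.3 ± 1.45 CPM (3.57 ± 0.27, adjusted p = 4.25e-06). MYC and ribosome biogenesis genes rose, 23 of 40 and 34 adjusted over the list alone, with a median of 1.12 (adjusted p = 1.58e-36, and 0.0179 with an estimated correlation). Myc went from 135 ± 2.63 to 413 ± 63.7 CPM (1.61 ± 0.22), and Heatr1 (1.60 ± 0.19), Utp20 (1.38 ± 0.19) and Nop2 (1.57 ± 0.23) rose. IL-7 and STAT5 targets had 8 of 22 members up and 1 down, 10 and 3 adjusted over the list alone, with a median of 0.67 (adjusted p = 3.09e-07, and 0.0179 with an estimated correlation). Cish (2.68 ± 0.26), Pim1 (2.30 ± 0.21) and the MAP kinase phosphatase gene Dusp5 (3.11 ± 0.31) rose, and Il7r stood at -0.76 ± 0.21 (adjusted p = 0.0520, and 0.0360 with the replicate block). The ATF4 list had 8 of 31 members up and 1 down, 9 and 1 adjusted over the list alone, with a median of 0.74 (adjusted p = 2.78e-07, and 0.00914 with an estimated correlation), for example Aldh18a1 (1.46 ± 0.20), Shmt2 (1.26 ± 0.22) and Mthfd2 (1.38 ± 0.29).

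Pro-B identity genes were lower after IL-7 in KO, with 5 of 28 down and none up, 1 up and 16 down adjusted over the list alone, and a median of -0.56 (adjusted p = 1.84e-11, and 0.0179 with an estimated correlation). Rag1 fell from 1633 ± 103 to 375 ± 8.91 CPM (-2.12 ± 0.22, adjusted p = 3.21e-05), and Rag2 (-1.87 ± 0.25), Cd93 (-1.48 ± 0.21) and Cd79b (-0.95 ± 0.23) fell. Pre-B differentiation genes were lower (4 of 30 down, 2 up and 7 down adjusted over the list alone, median -0.28, adjusted p = 3.48e-04, and 0.172 with an estimated correlation), with Sell (-2.17 ± 0.26) and Cd22 (-1.60 ± 0.30) among them. G2/M and mitosis genes had a median of -0.01 (1 of 36 fell, none adjusted over the list alone, adjusted p = 0.565), and were called lower without KO 0 h replicate 1 (0.00735). G1/S and DNA replication genes were lower (2 of 38 down, 3 adjusted over the list alone, median -0.39, adjusted p = 3.63e-06, and 0.523 with an estimated correlation). Glycolysis and hypoxia genes were higher (4 of 26 up, 9 adjusted over the list alone, median 0.54, adjusted p = 3.24e-06, and 0.0957 with an estimated correlation), Hk2 (2.17 ± 0.38) and Ldha (1.11 ± 0.22) rising. Interferon-stimulated genes were higher (3 of 38 up and 1 down, 3 and 2 adjusted over the list alone, median 0.54, adjusted p = 0.00198, 0.702 with an estimated correlation, 0.338 without KO 6 h replicate 2, and 0.235 without the sparsest libraries). Stat2 (1.25 ± 0.22) and Ifi44 (1.52 ± 0.37) rose and Ifit2 fell (-1.10 ± 0.28).

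Heat shock and protein folding genes were called higher in the KO response (3 of 23 up, 6 up and 2 down adjusted over the list alone, median 0.24, adjusted p = 0.00304, and 0.523 with an estimated correlation). They were not without KO 0 h replicate 1 (0.161) or KO 6 h replicate 1 (0.123), or without the libraries rich in Gm42418 (0.175). Zinc finger and homeobox genes were lower (1 of 29 fell, 1 adjusted over the list alone, median -0.22, adjusted p = 0.0299, and 0.327 with an estimated correlation). This was lost without KO 0 h replicate 1 (0.161) or KO 6 h replicate 1 (0.203), or without the libraries rich in Gm42418 (0.216). Across all genes 326 rose and 291 fell. The iodide transporter gene Slc5a5 was at 0 counts at 0 h and rose at least 132-fold to 10.0 ± 1.75 CPM (adjusted p = 0.0419). Lta (6.20 ± 0.75), Nr4a3 (6.07 ± 0.87), the semaphorin gene Sema6d (5.98 ± 0.66), Nrxn2 (5.36 ± 0.70) and Foxc1 (4.81 ± 0.95) rose. Fos (-4.24 ± 0.99), Cd180 (-3.41 ± 0.48), Mmrn1 (-3.25 ± 0.46), Rgs8 (-3.20 ± 0.73) and the transcription factor gene Maf (-3.20 ± 0.32) fell. The count of 617 was 1065 with DESeq2, 969 with no filter and 276 without the libraries rich in Gm42418. It was 1098 without WT 0 h replicate 1, 347 without KO 0 h replicate 1, 288 without KO 6 h replicate 1 and 278 without KO 6 h replicate 2, and 33 of 57 rule-picked genes past the threshold passed whichever library was left out.

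The responses of both genotypes share no libraries and overlapped. Of the 466 genes that rose in WT 218 also rose in KO (9.48 by chance), and of the 474 that fell 197 also fell (8.60 by chance). No gene rose in one genotype and fell in the other.

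**Figure D3:**
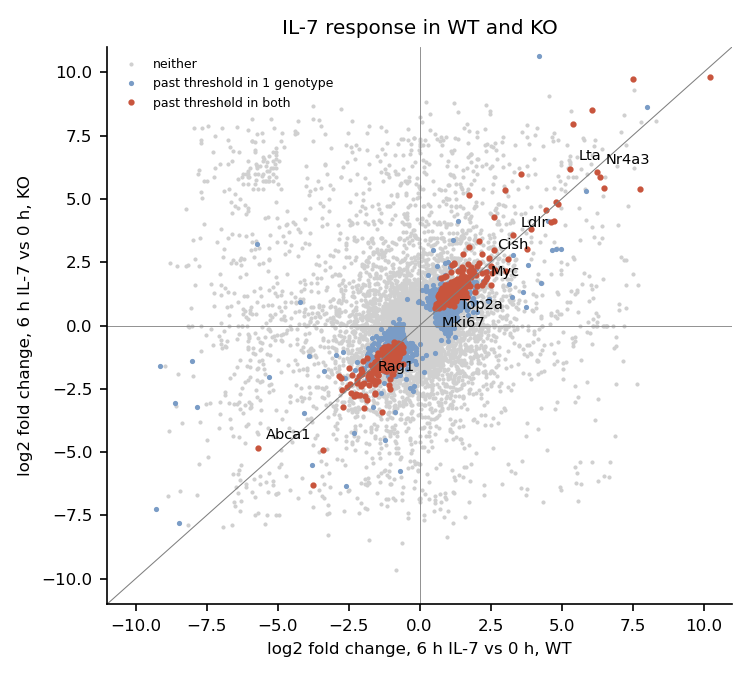
Log2 fold change after 6 h of IL-7 in WT (horizontal) and KO (vertical) for the 16033 genes tested (points), coloured by whether the adjusted p was under 0.05 in both genotypes, in 1 or in neither; the line marks equal change. The 218 shared rises and 197 shared falls lie in the upper right and lower left quadrants, with Ldlr at 3.28 and 3.57 and Top2a at 1.14 in WT.

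The response in KO minus the response in WT was tested to ask whether METTL14 changes how genes respond to IL-7. G2/M and mitosis genes responded less in KO, with a median difference of -0.82 over 36 members, 7 of which were lower adjusted over the list alone (adjusted p = 2.00e-24, and 0.426 with an estimated correlation). The kinetochore genes Cenpe (-1.46 ± 0.41) and Bub1b (-1.09 ± 0.31) and the spindle genes Hmmr (-1.24 ± 0.36) and Dlgap5 (-1.12 ± 0.32) had the smallest p of the list. Interferon-stimulated genes responded more in KO (4 of 38 higher adjusted over the list alone, median 0.72, adjusted p = 1.46e-09, and 0.723 with an estimated correlation), for example Ifit1 (2.71 ± 0.81), Mx2 (2.50 ± 0.76) and Zbp1 (1.51 ± 0.47). The ATF4 list responded more (median 0.29 over 31 members, adjusted p = 0.0306, and 0.426 with an estimated correlation), for example Mthfd2 (0.94 ± 0.37) and Aldh18a1 (0.68 ± 0.26). Cholesterol and lipid synthesis genes responded less (median -0.24 over 27 members, adjusted p = 0.00540, and 0.723 with an estimated correlation), for example Elovl6 (-0.94 ± 0.26) and Fdft1 (-1.01 ± 0.34). The number of lists called was 4, and 2 without WT 6 h replicate 3 or without KO 6 h replicate 1. The ATF4 difference was lost without WT 0 h replicate 1 (0.0778), KO 0 h replicate 1 (0.0648), KO 0 h replicate 2 (0.0821), WT 6 h replicate 1 (0.0916), WT 6 h replicate 3 (0.0537), KO 6 h replicate 1 (0.0507) or KO 6 h replicate 2 (0.0957), and without the sparsest libraries (0.144). The cholesterol difference was lost without WT 0 h replicate 3 (0.0582), KO 0 h replicate 1 (0.274), WT 6 h replicate 3 (0.0537) or KO 6 h replicate 1 (0.0763), and without the libraries rich in Gm42418 (0.143). No single gene passed in edgeR, where 729 had an unadjusted p under 0.05. EdgeR called 55 with no filter on low counts and, filtered, 2 without the sparsest libraries. DESeq2 called 1 gene and limma-voom 0, and edgeR called 1 without WT 0 h replicate 1. The smallest p were those of Hist1h2ao (-1.37 ± 0.27), BE692007 (2.54 ± 0.55), the cell-cycle inhibitor gene Cdkn2d (-1.66 ± 0.37) and Pag1 (1.13 ± 0.26). Genes induced by IL-7 over both genotypes (925) had a median difference of 0.0740 against 0.0198 in other genes (camera, adjusted p = 0.125), and genes repressed (981) one of -0.0507 against 0.0318 (camera, adjusted p = 0.125, unadjusted 0.0900). The first passed without WT 6 h replicate 3 (0.0329). The second passed without WT 0 h replicate 1 (0.00208), KO 0 h replicate 2 (1.69e-05), WT 6 h replicate 3 (0.0299) or KO 6 h replicate 2 (0.00505).

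The m6A IP and its input were compared to ask which transcripts carry m6A in WT cells. The immediate early and AP-1 list was enriched in the IP, 22 of 25 members higher and none lower with the same counts adjusted over the list alone, at a median of 2.08 (adjusted p = 9.94e-07, and 0.487 with an estimated correlation). Jun, a growth-response transcription factor gene, stood at 333 ± 50.3 CPM in the IP and 34.4 ± 6.25 CPM in the input (3.28 ± 0.20, adjusted p = 3.09e-05, chromosome 4, 95049036 to 95052222), and Jund (3.14 ± 0.19) and Ier5 (3.13 ± 0.17) were enriched. Zinc finger and homeobox genes were enriched (24 of 30, 25 adjusted over the list alone, median 1.61, adjusted p = 5.61e-08, and 0.487 with an estimated correlation), for example Zfp281 (2.81 ± 0.16) and Satb1 (2.24 ± 0.15). IL-7 and STAT5 targets were enriched (16 of 22 higher and 2 lower, 17 and 2 adjusted over the list alone, median 1.74, adjusted p = 0.00189, and 0.487 with an estimated correlation). Myc (1204 ± 377 against 339 ± 25.5 CPM, 1.83 ± 0.25, adjusted p = 4.07e-04), Il7r (2.18 ± 0.22, adjusted p = 8.17e-05), Mcl1 (2.11 ± 0.17) and Bcl2l1 (2.11 ± 0.18) were enriched, and Ccnd3 was depleted (adjusted p = 5.29e-05). Pro-B identity genes were enriched (18 of 27 higher and 8 lower, with the same counts adjusted over the list alone, median 1.15, adjusted p = 0.0369, and 0.487 with an estimated correlation). Rag2 (3.08 ± 0.18), Sox4 (3.03 ± 0.24), Vpreb2 (2.43 ± 0.18) and Foxo1 (2.16 ± 0.18) are examples.

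Chromatin enzymes were enriched in the IP (25 of 40 higher and 7 lower, with the same counts adjusted over the list alone, median 0.94, adjusted p = 0.00313, and 0.487 with an estimated correlation), among them Chd7 (2.44 ± 0.17), Ep300 (2.14 ± 0.17) and Crebbp (2.01 ± 0.16). Of m6A writers, readers and erasers 10 of 21 were higher and 5 lower, also adjusted over the list alone (median 0.30, adjusted p = 0.0153, and 0.487 with an estimated correlation). Rbm15b (3.27 ± 0.21), Rbm15 (2.65 ± 0.15), Ythdf2 (2.39 ± 0.17) and Wtap (1.32 ± 0.14) were enriched, and Mettl14 (-0.63 ± 0.21, adjusted p = 0.0299) and Mettl3 (-0.93 ± 0.17) were depleted. Cytosolic ribosomal protein genes were depleted, 44 of 45 also adjusted over the list alone, at a median of -1.90 (adjusted p = 4.64e-19, and 0.487 with an estimated correlation), for example Rps27a (-3.05 ± 0.20). Nuclear-encoded respiratory chain genes were depleted (33 of 39, median -1.44, adjusted p = 4.17e-10, and 0.487 with an estimated correlation), for example Cox4i1 (-2.32 ± 0.16). Glycolysis genes were depleted (18 of 25 lower and 3 higher, median -1.50, adjusted p = 0.00227, and 0.487 with an estimated correlation), with Ldha at -2.66 ± 0.19 and Vegfa at 2.82 ± 0.21. G2/M genes (26 of 36 lower and 7 higher, median -1.07, adjusted p = 5.17e-04, and 0.585 with an estimated correlation) and G1/S genes (25 of 38 lower and 7 higher, median -0.83, adjusted p = 0.00389, and 0.487 with an estimated correlation) were depleted. Ccna2 (-2.21 ± 0.16) and Pcna (-1.83 ± 0.15) are examples, while Mki67 (1.82 ± 0.27) and Fen1 (2.15 ± 0.19) were enriched. Histone genes were depleted (29 of 48 lower and 1 higher, median -1.43, adjusted p = 0.00394, and 0.487 with an estimated correlation), among them Hist1h2ag (-4.26 ± 0.27) and Hist1h2ah (-4.56 ± 0.33).

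Of 14309 genes tested, 4948 were enriched in the m6A IP and 4991 depleted. The strongest enrichments the naming rule allows were those of Zfp993 (4.14 ± 0.82), Sec62 (4.08 ± 0.33, 1770.1 ± 755 against 104 ± 0.944 CPM), Omp (4.07 ± 0.35), Armcx6 (4.05 ± 0.42), Jrkl (4.04 ± 0.24) and Gpatch4 (3.86 ± 0.34). The strongest depletions outside the lists were those of Rbm3os (-4.29 ± 0.32), Ldha-ps2 (-3.70 ± 0.32), Alg1 (-3.53 ± 0.29) and the small RNA Bc1 (-3.35 ± 0.28). The m6A inputs, of poly(A) RNA, differed from the YTHDF2 inputs in genes the naming rule lists. Rag1 stood at 46.8 ± 2.83 against 1132 ± 92.0 CPM, Il7r at 32.7 ± 4.30 against 334 ± 12.6, Myc at 339 ± 25.5 against 96.8 ± 0.530 and Cish at 66.0 ± 7.54 against 7.02 ± 2.70, each normalised within its own assay. Rag1 and Il7r were also below their WT levels in RNA-seq at 0 h. The sex of the mice differed too, as given below. Whether the m6A-seq cells were in another state was not tested, so genes enriched in this IP need not be those marked in the cells of the KO comparison.

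YTHDF2 RIP and its input were compared to ask which transcripts YTHDF2 binds in WT cells. B-lineage genes went both ways. Syk, a kinase of receptor signalling, stood at 4384 ± 125 CPM in the RIP and 1051 ± 12.9 CPM in the input (2.06 ± 0.09, adjusted p = 4.40e-08, chromosome 13, 52582610 to 52648792). Bach2 (1.92 ± 0.10), Ikzf1 (1.70 ± 0.10), Irf4 (1.43 ± 0.11), Il7r (1.35 ± 0.12), Pax5 (1.33 ± 0.10) and Rag1 (1.29 ± 0.12) were enriched, while Vpreb3 (-3.21 ± 0.16), Cd79a (-2.50 ± 0.14) and Pou2af1 (-1.60 ± 0.12) were depleted. The pro-B identity list had 10 members higher and 10 lower of 28 (median 0.16, mean -0.06, adjusted p = 0.939), and pre-B differentiation 8 and 8 of 30 (median -0.03, adjusted p = 0.583). Chromatin enzymes were enriched (30 of 40 higher and 3 lower, with the same counts adjusted over the list alone, median 1.31, adjusted p = 4.06e-18, and 0.142 with an estimated correlation), for example Kmt2d (2.66 ± 0.11) and Crebbp (2.11 ± 0.10). Zinc finger and homeobox genes were enriched (18 of 29, also adjusted over the list alone, median 0.95, adjusted p = 3.42e-06, and 0.142 with an estimated correlation), for example Zfp217 (2.03 ± 0.15) and Sp3 (1.56 ± 0.12). Ythdf2 was enriched (0.87 ± 0.17, adjusted p = 0.00175), and Myc stood at -0.13 ± 0.19 (adjusted p = 0.664).

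Cytosolic ribosomal protein genes were depleted from the RIP, all 45 of 45 also adjusted over the list alone, at a median of -3.32 (adjusted p = 3.71e-84, and 0.0510 with an estimated correlation). Rpl32 went from 345 ± 31.8 CPM in the input to 16.9 ± 1.65 CPM (-4.35 ± 0.19, adjusted p = 3.76e-08), and Rplp2 (-3.61 ± 0.14) and Rps20 (-3.61 ± 0.15) are further examples. Histone genes were depleted (51 of 53, also adjusted over the list alone, median -3.43, adjusted p = 4.14e-71, and 0.0573 with an estimated correlation), Hist1h3b among them (-4.40 ± 0.14). Nuclear-encoded respiratory chain genes were depleted (36 of 39, 37 adjusted over the list alone, median -2.86, adjusted p = 5.74e-23, and 0.103 with an estimated correlation), for example Cox4i1 (-3.67 ± 0.23). Genes of the mitochondrial genome were depleted (6 of 7, median -2.87, adjusted p = 1.11e-15, and 0.241 with an estimated correlation), mt-Cytb at -3.33 ± 0.11 among them. Heat shock and protein folding genes were depleted (13 of 20, 14 adjusted over the list alone, median -1.05, adjusted p = 0.00512, and 0.412 with an estimated correlation), for example Hspa8 (-1.41 ± 0.12). G1/S genes (19 of 38 lower and 6 higher, 22 and 6 adjusted over the list alone, median -0.56, adjusted p = 0.0476, and 0.726 with an estimated correlation) were depleted. So were immunoglobulin constant transcripts (2 of 5 lower, also adjusted over the list alone, median -1.68, adjusted p = 0.0476, and 0.387 with an estimated correlation). Both stood at 0.0518 with DESeq2 size factors.

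Of 11892 genes tested, 2239 were enriched in the RIP and 2208 depleted. The strongest enrichments the naming rule allows were those of Ppp1r26, with 3 counts in the input and 242 in the RIP (ratio 56.8, 95% counting interval 19.2 to 277), Plekhg1, with 3 and 233 (ratio 54.7, 18.5 to 267), Itpripl2 (4.92 ± 0.76), Zfp58 (4.84 ± 1.04), Zfp862-ps (4.82 ± 1.01) and Ttn (4.61 ± 1.05). The strongest depletions were those of the Y RNA Rny1, with 336 counts in the input and 1 in the RIP (ratio 477, 95% counting interval 85.1 to 18911), the RNase P RNA Rpph1 (-7.29 ± 0.25), the mitochondrial ribosomal RNA mt-Rnr2 (-6.41 ± 0.11), Smim11 (-5.79 ± 0.61), Smim8 (-5.47 ± 1.31) and S100a13 (-5.35 ± 0.67). Mitochondrial ribosomal RNA took 23.4 and 20.01% of the counts in the inputs and 0.411 and 0.404% in the RIP libraries.

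The m6A and YTHDF2 enrichments, which share no libraries, were compared across the 11228 genes tested in both, which are not independent replicates. Spearman's rho was 0.511 and Pearson's r 0.451. Of the 11228 genes 4221 were enriched in the m6A IP and 1590 also in the YTHDF2 RIP (832 by chance). Depleted in both were 1505 (768 by chance). Transcript length and RNA class were not tested as a source.

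**Figure D4:**
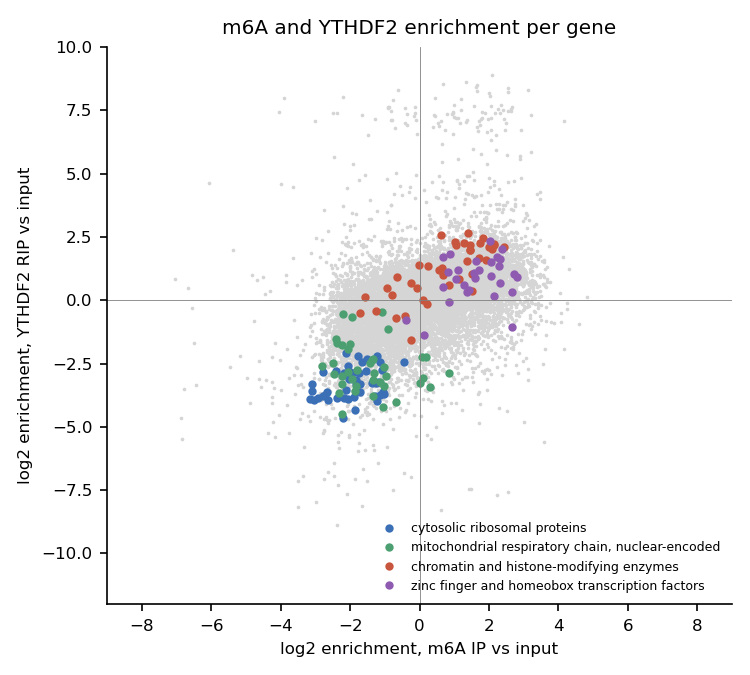
Log2 enrichment in the m6A IP over input (horizontal, n = 2 libraries each) and in the YTHDF2 RIP over input (vertical, n = 2 each) for the 11228 genes tested in both (grey points), with 4 gene lists in colour. Ribosomal protein genes have medians of -1.90 and -3.32, and chromatin enzymes 0.94 and 1.31.

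The genes enriched in the m6A IP or the YTHDF2 RIP were then followed in KO against WT, to ask whether they shift without METTL14. At 0 h the 4650 m6A-enriched genes measured had a median log2 fold change of 0.0810 against -0.0652 in 8182 other genes (camera p = 0.00133, adjusted over 4 tests 0.00531, 0.0274 with an estimated correlation). After 6 h the medians were 0.114 and -0.0255 (p = 0.0119, adjusted 0.0159, 0.0650 with an estimated correlation, 0.0522 without WT 6 h replicate 1 and 0.0620 without KO 6 h replicate 1). The 2227 YTHDF2-bound genes had medians of 0.00712 against -0.0327 at 0 h (p = 0.322, and 0.0466 without KO 0 h replicate 2) and 0.111 against -0.0122 after 6 h (p = 0.00530, adjusted 0.0106, 0.0946 with an estimated correlation, 0.0919 without KO 6 h replicate 1). After 6 h, 2.92% of the m6A-enriched genes rose against 0.990% of the others, and 1.48% fell against 1.87%. At 0 h 0.366% rose against 0.220%. Two-sided Fisher's exact tests, which wrongly take genes as independent, gave p = 1.82e-15, 0.121 and 0.158 in turn. Genes depleted from the YTHDF2 RIP, a test outside those 4, had a median of -0.165 against 0.0681 after 6 h (camera p = 3.70e-06, and 0.0469 with an estimated correlation), and of -0.0971 against -0.00301 at 0 h (0.00151, and 0.129 with an estimated correlation).

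**Figure D5:**
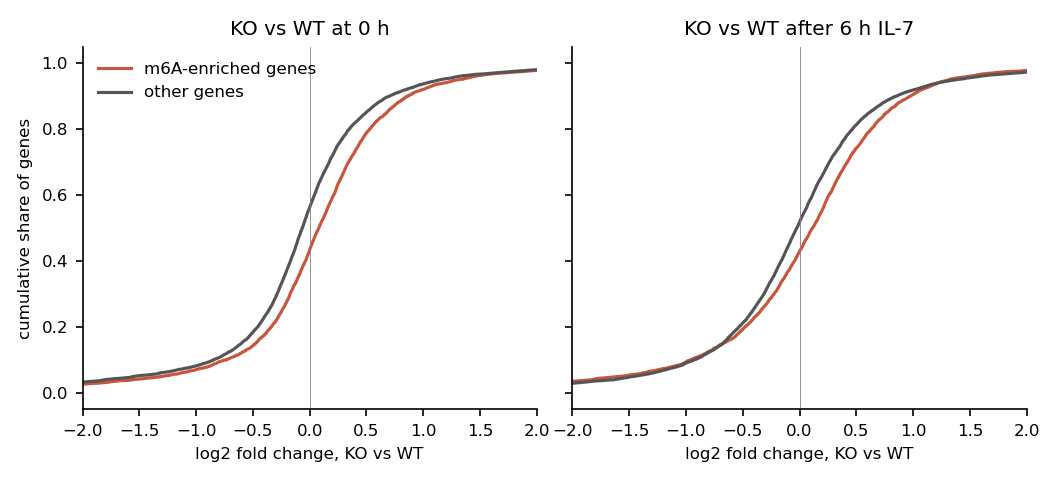
Cumulative share of genes by log2 fold change of KO against WT (WT n = 3, KO n = 2) at 0 h and after 6 h of IL-7, drawn from -2 to 2, for m6A-enriched genes (4650) and other genes tested in both assays (8182). The medians are 0.0810 and -0.0652 at 0 h and 0.114 and -0.0255 after 6 h.

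Other lists were measured as follows in KO against WT at 0 h and 6 h, and none passed in the fit as reported. Cytosolic ribosomal protein genes had medians of 0.09 and 0.08, p53 targets 0.13 and -0.09, immediate early genes 0.12 and -0.08, apoptosis regulators 0.04 and -0.04, glycolysis -0.03 and 0.20 (adjusted p = 0.0830 at 6 h, and 0.0445 with the replicate block), and immunoglobulin constant and germline transcripts 0.10 and 0.18. The mitochondrial genome list stood at 0.45 at 6 h (adjusted p = 0.0882), with scores of -0.54 and 0.83 in the KO libraries. It passed with the block (0.0462), without KO 0 h replicate 1 (0.0447), WT 6 h replicate 3 (0.0413) or KO 6 h replicate 1 (4.87e-05), and without the libraries rich in Gm42418 (5.56e-06). Other calls were gained with libraries left out. At 0 h ribosomal protein genes passed without WT 0 h replicate 1 (0.0172), KO 0 h replicate 1 (1.49e-06) or the sparsest libraries (0.0138). Immediate early (0.00370) and heat shock genes (1.57e-04) passed without KO 0 h replicate 1. Immunoglobulin transcripts passed without WT 0 h replicate 1 (0.00705), KO 0 h replicate 2 (0.0229), any WT 6 h library (0.0407 to 0.0463), KO 6 h replicate 2 (0.0349) or the sparsest libraries (0.0127). At 6 h glycolysis passed without WT 6 h replicate 2 (0.0216) or 3 (0.0413), and immunoglobulin transcripts without WT 6 h replicate 1 (0.0497). STAT5 targets (0.0454) and histones (0.0233) passed without KO 6 h replicate 1, and histones without the libraries rich in Gm42418 (0.0127). No list of cell-type markers passed between KO and WT at 0 h with all libraries. Neutrophil markers passed there without KO 0 h replicate 2 (2.61e-06), KO 6 h replicate 1 (0.0408) or KO 6 h replicate 2 (0.0347). KO 0 h replicate 1 stood apart in that list, with a score of 3.01 against -1.14 in replicate 2 and -1.85 to 0.53 in WT. In the same order of times, the medians were 0.50 and 0.49 for natural killer and innate lymphoid cells, 2.23 (2.03 with genes at 0 counts at their bound) and 0.78 for neutrophils, -0.13 and -0.06 for monocytes and macrophages, and 1.55 and -0.74 for dendritic cells. They were -0.22 and -0.55 (-0.08 at the bound) for mature B and plasma cells, -0.53 and -0.18 for small pre-B and immature B cells, -0.38 for large cycling pre-B cells at 0 h, and -2.57 (-0.61 at the bound) and -2.60 (-2.49 at the bound) for stroma and endothelium. In the IL-7 response monocyte and macrophage markers were lower in WT (median -1.72, adjusted p = 0.0476, 0.231 with an estimated correlation, and 0.0602 with the replicate block) and KO (median -1.51, adjusted p = 0.0197, and 0.153 with an estimated correlation). The WT call was lost without WT 0 h replicate 2 (0.163), WT 6 h replicate 1 (0.0809) or WT 6 h replicate 3 (0.0513), and the KO call without KO 0 h replicate 1 (0.0744). The lysozyme gene Lyz2 fell in WT from 27.2 ± 3.37 to 8.90 ± 1.62 CPM. Markers of large cycling pre-B cells were lower in the KO response (median -0.73, adjusted p = 0.0197, and 0.153 with an estimated correlation). It was lost without KO 0 h replicate 2 (0.0907) or KO 6 h replicate 1 (0.0903), the sparsest libraries (0.0840) or those rich in Gm42418 (0.0984). Fewer than 5 markers of T cells, erythroid cells, mast cells and basophils, or megakaryocytes were measured, too few to test.

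Some libraries stood apart. WT 0 h replicate 1 had 19.2% of the tested genes at 0 counts and KO 6 h replicate 2 had 12.4%, against 3.09 to 9.84% in the other RNA-seq libraries. Gm42418, a transcript that overlaps ribosomal RNA, took 8.62% of the counts in KO 6 h replicate 1 and 3.26% in WT 0 h replicate 2, and at most 0.167% in the other RNA-seq libraries. Genes of the sex chromosomes, looked at later, differed between assays (CPM over the library total). The Y-linked gene Ddx3y stood at 62.7 to 102 CPM in the RNA-seq libraries and at 0 counts in the YTHDF2 libraries, where Xist stood at 166 to 519 CPM. In m6A-seq replicate 1 had Ddx3y at 57.8 CPM in the input and 22.7 CPM in the IP, and replicate 2 had Xist at 1241 and 2666 CPM. The cells thus came from males in RNA-seq, females in RIP-seq and 1 of each in m6A-seq, and an effect of sex on comparisons between assays was not tested.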

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

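All tests of explanations in this part were chosen after the results were seen, except those of gene span and of other splits of the libraries. The 4 lists picked out here passed in camera for the difference of IL-7 responses, but none did with an estimated correlation.

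G2/M and mitosis genes responded at a median log2 fold change of 0.76 in WT and -0.01 in KO (called lower there without KO 0 h replicate 1, 0.00735), with a median of the differences per gene of -0.82 (adjusted p = 2.00e-24, 0.426 with an estimated correlation, 0.603 with fry), and their transcripts were lower in KO at 6 h (median -1.10, adjusted p = 6.89e-40, 0.110 with an estimated correlation). A single poor KO library was tested as the source: both KO libraries (-0.60 and -0.34) lay below the lowest WT library (0.35), with a gap of 0.691 against an SD of 0.293 among the WT libraries, which argues against it. Fewer cycling cells would lower G1/S genes too, and these had a median of -0.34 (quartiles -0.65 to -0.14) against -1.10 (-1.35 to -0.92) for G2/M genes. That lies between no fall and an equal fall, so fewer cycling cells and fewer of the cycling cells in G2/M cannot be told apart here.

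The ATF4 list responded at 0.40 in WT and 0.74 in KO, with a median of the differences per gene of 0.29 (adjusted p = 0.0306, 0.426 with an estimated correlation, 0.0348 with fry). Interferon-stimulated genes responded at -0.44 in WT and 0.54 in KO, with a median of the differences per gene of 0.72 (adjusted p = 1.46e-09, 0.723 with an estimated correlation, 0.795 with fry). Cholesterol and lipid synthesis genes responded at 1.67 in WT and 1.03 in KO, with a median of the differences per gene of -0.24 (adjusted p = 0.00540, 0.723 with an estimated correlation, 0.656 with fry).

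m6A-enriched genes were higher in KO than other genes at both times, by differences of medians of 0.146 at 0 h and 0.139 at 6 h. At 6 h camera p was 0.0119, 0.0650 with an estimated correlation and 0.0522 without WT 6 h replicate 1. Their expression level as the source was tested against 10000 random lists matched on mean expression, and the list median lay above all of them at 0 h (permutation p = 2e-04, the smallest they can give). Spread between libraries was tested with a score per library. Each KO library exceeded all WT libraries of its time, by 0.0951 at 0 h (WT SD 0.0554) and 0.102 at 6 h (SD 0.0383). Gene span was tested within 5 bins, where the mean difference was 0.158 at 0 h and 0.155 at 6 h. These argue against the 3 technical sources tested, and a slower decay of marked transcripts without METTL14 may be 1 explanation, untested here because decay was not measured.

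The count of genes that changed with IL-7 in WT was set against the other splits of the 6 WT libraries. The 10 splits are too few for a share under 0.05. The real split called 940 genes and the highest of the others 0.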

How the results depend on the processing

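Leaving out the sparsest libraries (WT 0 h replicate 1 and KO 6 h replicate 2) or those rich in Gm42418 (WT 0 h replicate 2 and KO 6 h replicate 1), and crossing the KO numbers, were alternatives chosen after the data were seen. The order of counts below is KO against WT at 0 h and 6 h, IL-7 in WT, IL-7 in KO and the difference of responses, against 58, 450, 940, 617 and 0 as reported. No filter on low counts gave 307, 1025, 1452, 969 and 55, and DESeq2 257, 969, 1477, 1065 and 1. An absolute log2 fold change above 1 gave 497 for IL-7 in WT. For KO against WT at 0 h limma-voom gave 32, and fits of only the groups compared gave 6 at 0 h and 965 at 6 h. Without the sparsest libraries the counts were 112 at 0 h, 188 at 6 h and 2 for the difference, and without those rich in Gm42418 23 at 0 h, 180 at 6 h and 276 for IL-7 in KO. DESeq2 size factors, the 1 CPM filter and library sizes without mitochondrial, ribosomal, small RNA and immunoglobulin genes kept every count of genes within 1.5 times. DESeq2 size factors ended the calls of the G1/S and immunoglobulin lists in the YTHDF2 RIP (0.0518 each). The m6A and YTHDF2 counts stayed within 1.5 times in all alternatives run. The cause of these moves was not tested.

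With 1 library left out the counts ran from 14 to 92 for KO against WT at 0 h, from 42 to 895 at 6 h, from 425 to 1074 for IL-7 in WT, from 278 to 1098 for IL-7 in KO, from 0 to 1 for the difference, from 7798 to 10752 for m6A and from 3320 to 5022 for YTHDF2. Mettl14 ran from -2.35 to -1.60 at 0 h and from -2.07 to -1.58 at 6 h. Rho between the m6A and YTHDF2 enrichments ran from 0.446 to 0.509.

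The number of gene lists called was 11, 8, 12, 11 and 4 in the RNA-seq contrasts, 12 for m6A and 9 for YTHDF2. With an estimated correlation these were 1, 1, 4, 5, 0, 0 and 0. With fry they were 2 for KO against WT at 0 h, 3 at 6 h, 6 for IL-7 in KO, 1 for the difference and 14 for YTHDF2. With 1 library left out the lists called ran from 8 to 12, 8 to 11, 12 to 14, 11 to 13 and 2 to 6 in the RNA-seq contrasts, and 8 were called for the difference without the sparsest libraries. The mitochondrial genome list changed sign for KO against WT at 0 h without KO 0 h replicate 1 (0.460, with 2.76e-06 to 0.558 over all libraries left out in turn), for the difference without that library (0.0338, with 1.43e-05 to 0.949), and without the libraries rich in Gm42418 for IL-7 in KO (0.0340) and the difference (2.43e-04). The cause was not tested. List calls ended by leaving out the sparsest libraries or those rich in Gm42418 are given with the results.

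Camera p for m6A-enriched genes in KO ran from 5.06e-04 to 0.0168 at 0 h and from 0.00712 to 0.0620 at 6 h with 1 library left out. At 6 h it was 0.0650 with an estimated correlation and 0.112 for the 1000 largest enrichments. The p of fry, which tests the set against no change, was 0.0556 at 0 h and 0.0704 at 6 h. For YTHDF2-bound genes the camera p ran from 0.0466 to 0.844 at 0 h, with 0.0147 for genes in both lists among all genes tested in RIP-seq and 2e-04 against random lists, the smallest they can give, and from 5.86e-04 to 0.0919 at 6 h, with 0.0946 under an estimated correlation. For genes induced by IL-7 the p for the difference ran from 0.0329 to 0.974 and for repressed genes from 1.69e-05 to 0.775.

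The replicate block gave 82 and 363 genes for KO against WT at 0 h and 6 h, 1003 and 653 for IL-7 in WT and KO, and 0 for the difference. Within genotype it gave 1079, 692 and 0. It gave 10731 genes for m6A and 4723 for YTHDF2. In WT, where pairing is left open, the block moved no count of calls over 1.5 times. It ended the calls of the IL-7 and STAT5 list (0.0615) and the histone list (0.0604) for KO against WT at 0 h and of monocyte markers for IL-7 in WT (0.0602). Calls it added are given with the results. KO 0 h and 6 h libraries of the same number had a correlation of -0.32, and with the KO numbers crossed 1309 genes were called for IL-7 in KO. m6A inputs and IPs of the same number, which share the sex of the mice, had a correlation of 0.57 and YTHDF2 inputs and RIPs one of 0.0955, with 2 pairs each. The difference of responses needs all groups, so the fit of only the groups compared was not run for it.

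Over all settings, values for single genes kept their direction and side of the threshold in 8968 cases, lost the call in 572, gained it in 175 and reversed in 0, where a change of sign between uncalled values counts as no change. For single lists the numbers were 2360, 149, 101 and 4.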

Other observations

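The tests in this part were chosen after the results were seen, as were its genes. They concern a segment around Mettl14, the share of pseudogenes, the loss of Mettl14 and shared reads. Cd79a, which encodes a signalling chain of the pre-B cell receptor, stood at 438 ± 139 CPM in KO against 987 ± 263 CPM in WT at 0 h (log2 fold change -1.17 ± 0.29, adjusted p = 0.126) and at 230.3 ± 95.5 against 572 ± 78.2 CPM at 6 h (-1.31 ± 0.29, adjusted p = 0.0290). Its partner Cd79b stood at 0.10 ± 0.21 and 0.01 ± 0.21, and why Cd79a fell was not tested. The receptor genes Csf2rb and Csf2rb2 were higher in KO at both times, the first by 1.04 ± 0.21 at 0 h and 0.93 ± 0.21 at 6 h and the second by 1.59 ± 0.28 and 1.39 ± 0.28. Both rose with IL-7 in WT (1.55 ± 0.20 and 1.76 ± 0.26) and in KO (1.44 ± 0.24 and 1.56 ± 0.32). Il9r had 0 counts in WT and 142 in KO at 0 h, at least 72.3-fold more (adjusted p = 0.0873), and 1 and 180 counts at 6 h, a ratio of 312 (95% counting interval 55.3 to 12392, adjusted p = 0.0383). Iglc3, a light chain constant gene, was higher in KO at 0 h (40.7 ± 11.3 against 1.67 ± 1.34 CPM, adjusted p = 0.0463) and at 6 h (28.9 ± 16.2 against 1.22 ± 0.670 CPM, adjusted p = 0.0171, and 0.0696 with the replicate block).

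T cell receptor gamma constant genes rose with IL-7 in both genotypes. Tcrg-C1 went from 1.55 ± 1.62 to 43.5 ± 4.05 CPM in WT (log2 fold change 4.80 ± 0.75, adjusted p = 0.00586) and from 2.48 ± 2.31 to 72.7 ± 16.2 CPM in KO (4.87 ± 0.91, adjusted p = 0.0191). Tcrg-C2 rose by 6.51 ± 0.95 in WT and 5.42 ± 1.07 in KO, and Tcrg-C3 by 6.09 ± 1.02 in WT, while in KO it went from 3 counts to 1117, a ratio of 416 (95% counting interval 142 to 2020). With IL-7 the cholesterol exporter gene Abca1 fell by 5.69 ± 0.59 in WT and 4.83 ± 0.70 in KO, Abcg1 by 2.76 ± 0.25 and 2.06 ± 0.29, and Mylip, which marks the LDL receptor for degradation, by 1.79 ± 0.21 and 2.37 ± 0.26.

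Between KO and WT 21 genes differed over 4-fold at both times, 12 higher and 9 lower, and passed the threshold at 6 h. A segment of the genome carried along with the Mettl14 allele was tested as the source for all of them. Of the 19 with a position 1, Cd2, lay within 25 Mb of Mettl14, and 3.10% of the tested genes within 25 Mb were called at either time against 3.16% elsewhere (Fisher's exact test, two-sided, p = 1), which argues against it. Pseudogenes were 5 of the 12 higher genes against 1381 of the 16033 tested (8.61%, Fisher's exact test, p = 0.00223). Levels of single libraries that follow are CPM over the library total, without TMM factors. Gm9625 ranged from 54.3 to 84.0 CPM in KO and from 0.504 to 2.55 CPM in WT RNA-seq libraries. The loss of Mettl14 as the source was tested in the YTHDF2 inputs, which are labelled WT: Gm9625 stood at 1.25 and 46.4 CPM and Gm8730 at 0.625 and 24.1 CPM, a ratio of at least 37.1 between replicates whose Mettl14 stood at 50.5 and 62.1 CPM. Gm8730 also stood at 851 CPM in each m6A input, which is poly(A) RNA from WT. A single input library stood apart, and how reads that map to several places were counted is not described, so the loss of Mettl14, another difference between samples and shared reads cannot be told apart. For Rplp0-ps1, reads shared with its parent gene Rplp0 were tested on that gene, which had a log2 fold change of -0.0128 ± 0.192 where -0.0204 would be needed, so this explanation cannot be told apart from a change of the pseudogene itself. It was not tested for Gm5948 and Tdpx-ps1.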
